A study of Macaca fascicularis with 21 samples.

How the data were processed

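Single cells of cynomolgus monkey (Macaca fascicularis) embryos were profiled by RNA sequencing. Per the labels' protocols, blastocysts without their zona pellucida were grown singly on Matrigel, a basement membrane gel, in medium whose serum content was raised with time. The implantation site was dissected and extra-embryonic cells were taken away before digestion, and single cells were then picked by hand into lysis buffer. Shares of cell types therefore describe the picked cells, not whole embryos. The RNA was reverse transcribed with template switching, barcoded, amplified and read at the 3' end, with pools of up to 96 barcoded cells, so a count measures the 3' part of a transcript.

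The deposited table holds whole-number counts for 30792 genes in 1453 cells, per the file headers, with a second table that gives each cell a day and a cell type, both assigned by the authors. STAR, an aligner, is the only tool listed, per the submitters' processing notes. Its version, the genome build, the read counter, the filters on cells and whether reads were collapsed to molecules are not given in the sources used here. Intervals from counts therefore cover counting error only, since copies made by PCR are not independent molecules. Totals per cell ran from 3376 to 483669 counts (median 61090.0), and genes with a count per cell from 2018 to 13219 (median 6399.0). No further filter on cells was applied. No pair of cells had identical values, and the day of all 1453 cells equalled the day in the labels of their embryo. No doublet caller was run, because cells were picked singly.

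Each of the 21 samples is 1 embryo, and the embryo was the replicate throughout. The labels give days 11, 12, 13, 14, 16 and 17 with 2, 5, 3, 4, 4 and 3 embryos. For 5 embryos (day 12 replicate 1, day 13 replicates 1 and 2, day 17 replicates 1 and 2) the day stands under a culture stage label, and for the other 16 under a developmental stage label. Whether both labels count from the same start is not given in the sources used here. No label names a sequencing batch, so the label type was used as the only known split, and within-label values are given where it holds enough embryos.

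The 12 annotated types were merged into 7 families, read here as epiblast (EPI: postE-EPI, postL-EPI), gastrulating cells (Gast: E-Gast, L-Gast1, L-Gast2), amnion (AM: E-AM, L-AM1, L-AM2), primordial germ cells (PGC: E-PGC), visceral or yolk sac endoderm (VE/YE), extraembryonic mesenchyme (EXMC) and trophoblast (TE: TE and derivatives). The annotation was made from the same expression values that are tested here, so a marker gene that differs between types is not independent evidence for the type.

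Of the gene names, 16890 were numbered identifiers with the prefix LOC, which hold 34.28% of all counts. Through gene identifiers of the RefSeq table for assembly T2T-MFA8v1.1, 3273 of them were given a symbol, which left 6.96% of counts without one. Coordinates from that assembly were not used, because the build of the counts is not named. Among the genes named in the text, BNIP3, CA3, CXCL14, CYP26A1, DCN, DNAJB9, FEN1, GATA2, IGF2, IGFBP5, KDM3A, LEF1, LUM, P4HA1, SLIT2, SOX17 and TPX2 are stored under such identifiers, and TBXT as T. The table has 14 features whose names had become dates, with 0.027% of counts, and these were kept unnamed. Reads shared with near-identical copies may be split between features, since the rule of the counter is not known, and this holds for multigene families such as HOX, KRT and NLRP genes and for LHB among the glycoprotein hormone subunits.

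Counts were summed per embryo, or per embryo and family with at least 5 cells. Sums of subtypes used at least 3 cells, because too few embryos held 5 cells of both subtypes. Genes were kept by filterByExpr and scaled with the trimmed mean of M values (TMM). They were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of single genes in the text come from this edgeR test. Day was a number, so a change is in log2 units per day. Each type was compared with EPI of the same embryos, and subtypes of a family with each other, with the embryo as a block, because the cells of one embryo share it. The difference between types in the change with day was tested as an F-test of the day by type terms with the embryo as a block. Values after ± are standard errors for log2 changes and standard deviations between embryos for CPM (counts scaled to a library of 1e6, from TMM-scaled sums) and for shares. A gene with no count in 1 group is given as a bound against 3 counts in the summed group, and one with 1 to 3 counts as a ratio of summed counts with its 95% exact counting interval.

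Shares of each family were related to day with Spearman's rho and Pearson's r, 2-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment over the 7 families; 1e-05 is the smallest p they can give. Whether the embryos of one day differed in their shares was tested with a chi-square statistic and 10000 resamples of cells.

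There were 29 gene lists for lineages, signalling pathways, metabolism, cell cycle and stress. They were set before the data were examined, as were the comparisons, the markers and the alternatives, apart from those named as added below; tests chosen later are named where they are used. Each list with at least 3 measured members was tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The genes named are, in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM and a symbol that is not a ribosomal, mitochondrial or numbered name; the 3 members with the lowest p of up to 6 lists that passed camera; and fixed lineage genes. For the day by type test they are the 12 genes with the lowest p. Not every gene that this rule selects is printed.

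Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, limma on log2(CPM + 1), 10 or 3 cells per sum, days 11 to 13 against 14 to 17, developmental stage labels alone, the label type as a covariate, no embryo block, the EPI share as a covariate, and leaving out each embryo in turn. Fits without day 16, and counts without genes at least 8 times higher in another type, were added after seeing the data. Every fit was tested on simulated data with 200 changed genes. Of 100 genes with a log2 change of 2, or of 4, between the groups or over the whole span of days, 70 and 94 were recovered for EXMC against EPI, 36 and 84 for EPI against day, 9 and 79 for VE/YE against day, 16 and 60 for PGC against EPI and 7 and 36 for L-AM2 against L-AM1. Between 1 and 4 of the calls in these and the other simulations were false. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the shares, cell values and figures.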

Results

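Embryos of the cynomolgus monkey were grown in culture past the blastocyst stage, and 1453 picked cells of 21 embryos were sequenced on labelled days 11, 12, 13, 14, 16 and 17. The series asks how such embryos develop through gastrulation, the stage at which the epiblast gives rise to the germ layers. Each embryo contributed 22 to 88 cells and 2540816 to 11857191 counts. The deposited annotation held 304 EPI, 83 Gast, 82 AM, 18 PGC, 485 EXMC and 380 TE cells, with 49 VE/YE cells up to day 14 and 52 later. Labels with the prefix E- or postE- stood at days 11 to 14 for all types but E-PGC, whose 18 cells all came from day 16. Labels with the prefix L- or postL- stood at days 16 and 17, except for 3 cells of 1 day 13 embryo.

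Markers fixed beforehand were looked up across the annotated types. Highest in their own family were all 6 markers of EXMC, all 6 of TE, all 5 of PGC, 7 of 8 of VE/YE (not AFP) and 5 of 7 of AM (not TFAP2A or GATA3). Of 6 epiblast markers, SOX2, DPPA4 and DNMT3B were highest in EPI, while POU5F1, NANOG and GDF3 were highest in other types. Of 6 streak markers, MIXL1, EOMES and MESP1 were highest in Gast, while TBXT, SNAI2 and TBX6 were not. Because the types were named from these same values, the match is no independent evidence for the names.

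**Figure D1:**
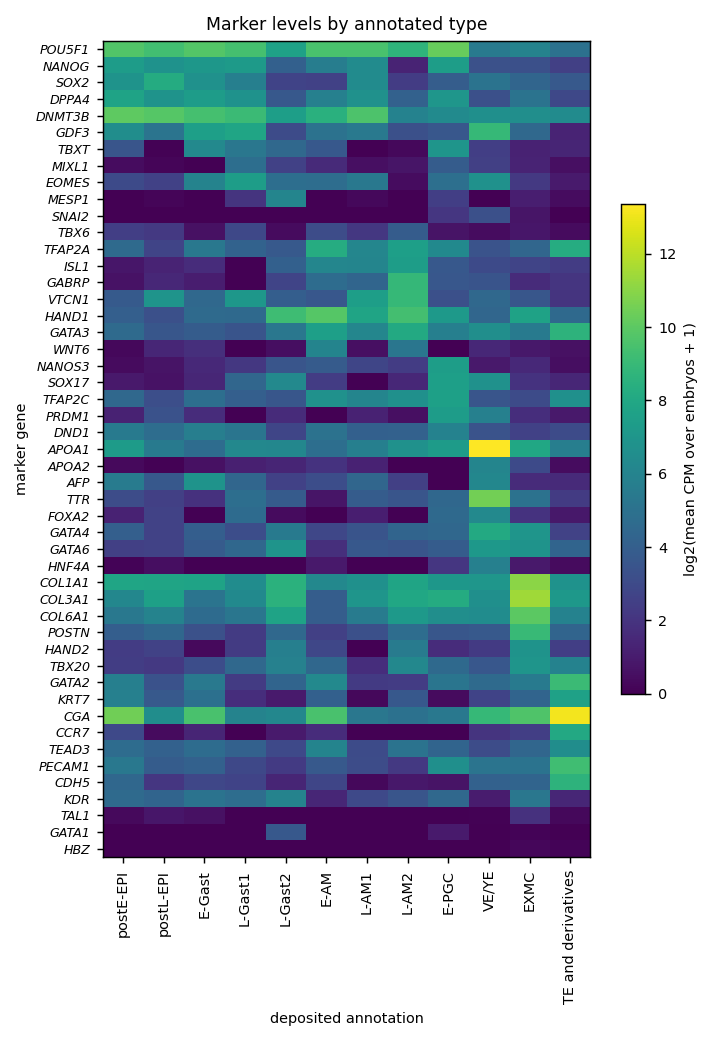
Marker level of each annotated type, as log2 of the mean CPM over embryos plus 1 (color), with marker genes in rows and deposited types in columns. CGA is brightest in TE and is also seen in postE-EPI, E-Gast, E-AM, VE/YE and EXMC, and APOA1 is brightest in VE/YE.

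How the make-up of the picked cells moved with day was asked over the 21 embryos. TE cells, the outer lineage that forms placenta, made up 59.3% ± 9.79 of an embryo's cells at day 11 (n = 2), 19.2% ± 3.47 at day 14 (n = 4), 0.900% ± 0.604 at day 16 (n = 4) and 9.08% ± 2.70 at day 17 (n = 3). EXMC cells, which line the extraembryonic cavities, were 14.4% ± 5.88 of cells at day 11, 25.6% ± 1.84 at day 16 and 67.3% ± 11.5 at day 17. EPI cells ranged from 9.77% ± 6.68 at day 13 (n = 3) to 30.0% ± 3.67 at day 16. PGC cells were seen in the 4 embryos of day 16 alone, at 5.42% ± 3.03, with 0 in the other 17 embryos. In the embryo of day 17 with the most cells, 0 of 86 cells leaves a share of up to 4.20% inside the exact 95% interval.

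The TE share fell with day (Spearman's rho = -0.796, permutation p = 4e-05, adjusted over 7 families 0.00028; Pearson's r = -0.796, permutation p = 3e-05, adjusted 0.00021). Without the 2 embryos farthest from the median day r was -0.748 (permutation p = 0.00027), and among the 16 embryos with developmental stage labels rho was -0.872 (permutation p = 2e-05). In the 5 embryos with culture stage labels rho was -0.791 for TE and 0.791 for EXMC (exact permutation p = 0.133 for each, with 0.0667 the smallest possible). The EXMC share (rho = 0.511, permutation p = 0.0198, adjusted 0.0694; r = 0.481, adjusted 0.0879) and the PGC share (rho = 0.445, permutation p = 0.0421, adjusted 0.0983; r = 0.448, adjusted 0.0879) missed the threshold after adjustment. Without the 2 farthest embryos r was 0.422 for EXMC and 0.438 for PGC, and with developmental stage labels alone rho was 0.375 (permutation p = 0.156) and 0.633 (permutation p = 0.00666, adjusted 0.0233), which passes for PGC. That set leaves out replicates 1 and 2 of day 17, which held 0 PGC cells, so the pass does not show a rise beyond day 16. EPI, Gast, AM and VE/YE had adjusted permutation p between 0.355 and 0.530. The embryos of one day differed beyond the sampling of cells at day 13 (Cramer's V = 0.423, permutation p = 0.0001, the smallest possible), day 14 (V = 0.460, p = 0.0001) and day 17 (V = 0.210, permutation p = 0.0183), but not at days 11, 12 and 16 (permutation p = 0.434, 0.127 and 0.798). At day 14 the EXMC share of single embryos ran from 2.35% to 78.7%.

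**Figure D2:**
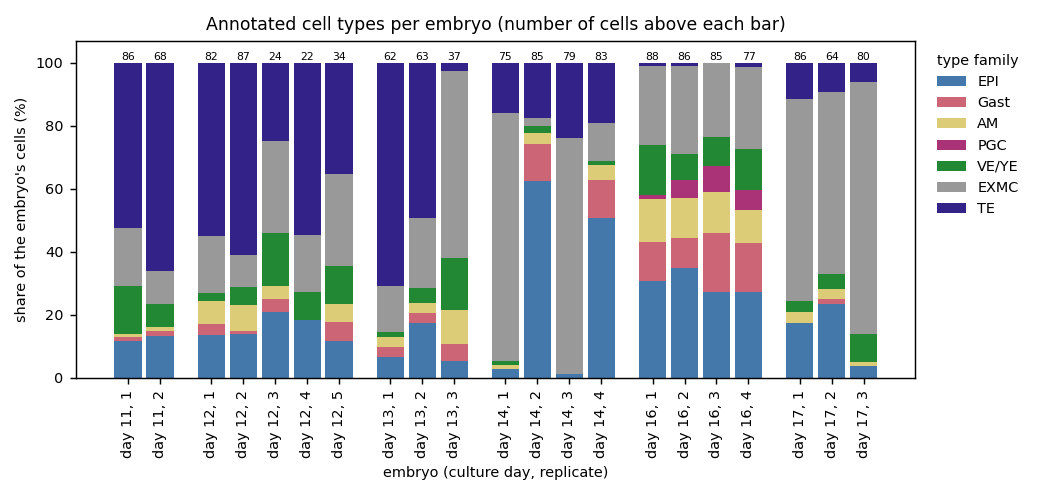
Share of each type family among the cells of each of the 21 embryos, in percent, ordered by day and replicate, with the number of cells above each bar. TE falls from 59.3% at day 11 to 0.900% at day 16, and the 4 embryos of day 14 differ from one another more than those of day 16.

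Summed over all cells of an embryo, CGA, NPPA and CCR7 fell and DLK1, CCL2 and COL1A1 rose from day 11 to day 17. CGA, the alpha subunit of chorionic gonadotropin, changed by -1.28 ± 0.19 log2 per day (adjusted p = 9.47e-05), from 10510 ± 1447 CPM at day 11 (n = 2) to 92.4 ± 87.1 at day 16 (n = 4). NPPA, the atrial natriuretic peptide, changed by -1.98 ± 0.32 per day (adjusted p = 1.95e-04) and CCR7, a chemokine receptor, by -1.52 ± 0.24 (adjusted p = 1.75e-04). DLK1, an imprinted growth regulator, rose by 1.27 ± 0.17 (adjusted p = 4.18e-05), the chemokine CCL2 by 1.45 ± 0.19 (adjusted p = 2.11e-05) and COL1A1, a chain of type I collagen, by 0.77 ± 0.13 (adjusted p = 3.42e-04). These sums mix the change within types with the change of their shares.

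Of 15924 genes tested across the 21 embryos, edgeR called 3488, of which 1814 rose and 1674 fell, and 5573 had an unadjusted p under 0.05. Among the largest rises were also DCN (1.41 ± 0.41 per day), GYS2 (1.63 ± 0.47), SP140L (1.46 ± 0.28) and CA3 (1.34 ± 0.31). The last 3 peaked at day 16, GYS2 at 111 ± 155 CPM against 1.103 ± 1.358 at day 17, SP140L at 130.2 ± 121 against 6.29 ± 8.54 and CA3 at 74.3 ± 41.5 against 10.1 ± 10.3, and were not called without day 16. Among the largest falls were also PLK5 (-1.87 ± 0.40), PRR9 (-1.57 ± 0.28), LHB (-1.49 ± 0.32) and C1H1orf116 (-1.46 ± 0.18). Of the 16 measured members of the trophoblast list 11 fell and 5 were not called, with 13 falls adjusted over the list alone. PGF, a growth factor of placental vessels, changed by -0.75 ± 0.11 and GATA3 by -0.46 ± 0.07. Of 13 mesenchymal transition genes 7 rose (9 adjusted over the list alone), VIM by 0.45 ± 0.09. Of 13 genes of primed pluripotency 6 rose (7 adjusted over the list alone), CRABP1 by 0.87 ± 0.09. Of 17 hypoxia targets 8 rose and 1 fell (8 and 1 adjusted over the list alone), P4HA1 by 0.52 ± 0.06. Camera placed these lists at adjusted p = 7.46e-11 (trophoblast), adjusted p = 2.65e-05 (mesenchymal transition), adjusted p = 4.32e-05 (primed pluripotency) and adjusted p = 0.00663 (hypoxia). None passed with an estimated correlation (adjusted p = 0.209, 0.462, 0.352 and 0.462 with an estimated correlation). Among the 16 embryos with developmental stage labels 2688 genes were called, and 3767 with the label type as a covariate. Without the 4 embryos of day 16 the count fell to 2266. With 1 embryo left out, the call was lost in 1 of 21 fits for GYS2.

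In EPI, the cells that form the embryo proper, genes of naive pluripotency fell with day and genes of primed pluripotency rose. OOEP and KHDC3L, parts of the maternal complex under the egg surface, changed by -1.36 ± 0.14 and -1.37 ± 0.33 log2 per day (adjusted p = 7.24e-05 and 0.0381). OOEP stood at 752 ± 62.0 CPM at day 11 (n = 2) and 3.74 ± 5.28 at day 17 (n = 2). DPPA5 and DPPA3, genes of the early pluripotent state, changed by -0.99 ± 0.17 and -0.84 ± 0.14 (adjusted p = 0.00545 and 0.00139), DPPA5 from 1819 ± 116 to 4.20 ± 2.17 CPM. SFRP1, a secreted WNT antagonist, rose by 1.06 ± 0.09 (adjusted p = 7.92e-06), from 18.9 ± 7.75 to 1051 ± 104 CPM. The transcription factors OTX2 and ZIC2 rose by 0.95 ± 0.15 and 0.73 ± 0.12 (adjusted p = 0.00196 and 0.00150). POU5F1 (-0.10 ± 0.07, adjusted p = 0.465) and NANOG (-0.10 ± 0.19, adjusted p = 0.832), which hold the pluripotent state, were not called. POU5F1 stood at 1040 ± 63.9 CPM at day 16 (n = 4) and 253 ± 38.3 at day 17 (n = 2), and NANOG at 215 ± 123 and 5.00 ± 1.99. SOX2 rose by 0.34 ± 0.09 (adjusted p = 0.0440), a call that was lost in 10 of the 14 fits without 1 embryo.

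The largest rises in EPI were those of BHLHE41, a clock repressor (2.25 ± 0.38 per day), TXNIP, which binds thioredoxin (1.31 ± 0.22), HEPH, a copper ferroxidase (1.23 ± 0.21), CYP26A1, which breaks down retinoic acid (1.16 ± 0.26), the membrane protein FLRT3 (1.13 ± 0.16) and SEMA5B, a semaphorin (adjusted p = 0.00186). The adjusted p of the others ran from 4.03e-04 for FLRT3 to 0.0252 for CYP26A1. BHLHE41 had no count at day 11, stood at 36.0 ± 10.2 CPM at day 16 and at 7.42 ± 0.673 at day 17. The largest falls also held NLRP7, a maternal-effect gene (-1.47 ± 0.20), PHOSPHO1 (-1.40 ± 0.24), NPPA (-1.35 ± 0.21) and the homeobox gene VENTX (-1.25 ± 0.18). Of 8 measured genes of naive pluripotency 3 fell (5 adjusted over the list alone), the third being TBX3 (-0.74 ± 0.17), with camera adjusted p = 6.97e-08, and 0.00785 with an estimated correlation. Of 13 genes of primed pluripotency 5 rose (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 4.05e-04, and 0.0247 with an estimated correlation). Of 7 measured germ cell genes 3 fell, DPPA3, SOX15 (-0.74 ± 0.15) and PDPN (-0.38 ± 0.08), with 3 adjusted over the list alone and camera adjusted p = 1.2e-05, and 0.0247 with an estimated correlation.

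Genes of extraembryonic types also moved in EPI. Of 12 measured trophoblast genes CCR7 (-1.02 ± 0.19) and CGA (-0.84 ± 0.19) fell (4 adjusted over the list alone; camera adjusted p = 2.66e-06, and 0.0692 with an estimated correlation), CGA from 1211 ± 6.81 CPM at day 11 to 129.7 ± 191 at day 16. A CGA count was present in 170 of 170 EPI cells of days 11 to 14 (median 1037 CPM) and in 356 of 356 TE cells of those days (median 7924 CPM), with a median of 57125.5 and 70056 counts per cell. Of 16 measured EXMC genes LUM (0.84 ± 0.15) and DCN (0.86 ± 0.17), proteoglycans of collagen fibres, rose (9 adjusted over the list alone; camera adjusted p = 7.58e-05, and 0.232 with an estimated correlation). At day 16 the levels of 16 EXMC genes in EPI were a median of 2.85% of those in EXMC of the same day. Of 15 hypoxia targets KDM3A (0.49 ± 0.11) and P4HA1 (0.49 ± 0.12) rose (4 adjusted over the list alone; camera adjusted p = 0.00198, and 0.188 with an estimated correlation). P4HA1 stood at 371 ± 128 CPM at day 16 and 89.98 ± 14.78 at day 17.

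Over 14 EPI sums with 284 cells, 442 of 11589 genes were called, of which 225 rose and 217 fell. An unadjusted p under 0.05 was seen for 2204. Both EPI sums of day 17, and 1 each of days 12 and 13, came from embryos with culture stage labels. Among embryos with developmental stage labels, which end at day 16 in EPI, 418 genes were called, and 599 with the label type as a covariate. Without genes at least 8 times higher in another type 394 were called, without day 16 the count was 143, and without replicate 3 of day 16 it was 275. Without day 16 the calls of CYP26A1, NLRP7, PHOSPHO1, KHDC3L, DPPA5, TBX3, CCR7, CGA, KDM3A, P4HA1 and SOX2 were lost, POU5F1 was called (-0.32, adjusted p = 0.0123), and BHLHE41, TXNIP, HEPH, FLRT3, SEMA5B and DCN were too low to be tested. Leaving out 1 embryo ended the call in 8 of 14 fits for KHDC3L, 6 of 14 fits for P4HA1, 3 of 14 fits for CGA and 2 of 14 fits for CYP26A1.

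**Figure D3:**
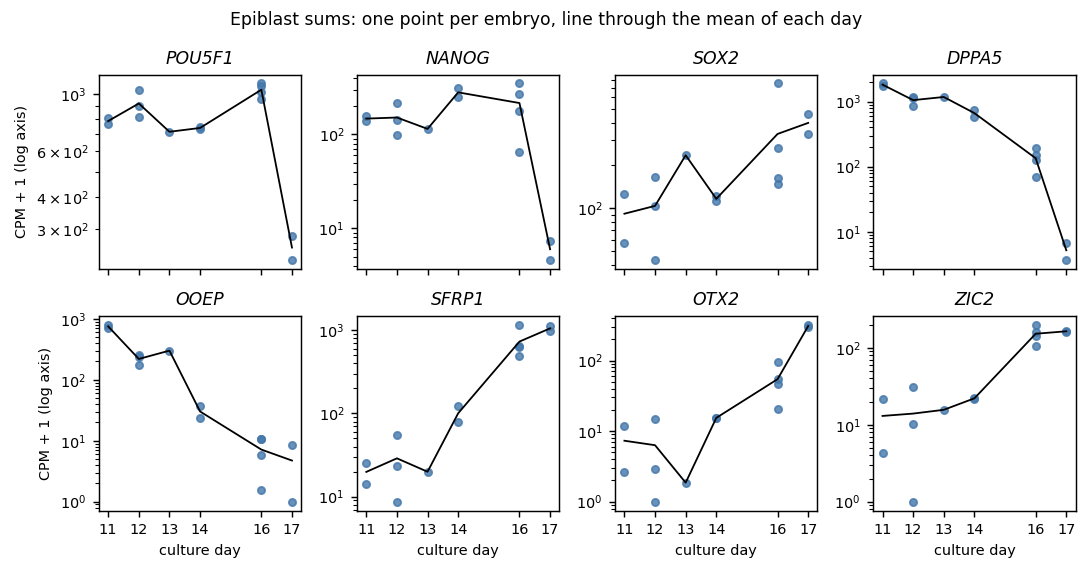
CPM plus 1 of 8 genes in EPI sums against labelled day (log axes that differ between panels), with a point for each of 14 embryos and a line through the mean of each day. DPPA5 and OOEP decline over the days, SFRP1, OTX2 and ZIC2 climb, and POU5F1 and NANOG lie lower at day 17 than at day 16.

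In EXMC, DLK1, COL1A1 and IGF2 rose with day and genes of S phase fell. DLK1 rose by 1.54 ± 0.15 log2 per day (adjusted p = 2.35e-06), from 2.22 ± 3.14 CPM at day 11 (n = 2) to 321 ± 117 at day 17 (n = 3). COL1A1 rose by 0.68 ± 0.09 (adjusted p = 7.58e-05), from 200.1 ± 44.3 to 4789 ± 920.2 CPM. IGF2, a fetal growth factor, rose by 1.07 ± 0.18 (adjusted p = 0.00136). The protease ADAMTS12 (1.44 ± 0.14), the guidance factor SLIT2 (1.45 ± 0.19), SFRP1 (1.39 ± 0.12), the chemokine CXCL14 (1.40 ± 0.27) and DCN (1.37 ± 0.32) made up the rest of the largest rises. The transcription factors HAND1 (-0.30 ± 0.07, adjusted p = 0.00707) and GATA4 (-0.26 ± 0.07, adjusted p = 0.0216) fell and GATA6 was not called (-0.03 ± 0.06, adjusted p = 0.797).

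Of 17 S phase genes 6 fell in EXMC (9 adjusted over the list alone), among them PCNA, the replication clamp (-0.35 ± 0.05, adjusted p = 1.2e-04), the helicase subunit MCM4 (-0.31 ± 0.05) and FEN1 (-0.31 ± 0.06), with camera adjusted p = 1.92e-09, and 0.0144 with an estimated correlation. Of 14 hypoxia targets 10 rose (12 adjusted over the list alone; camera adjusted p = 4.4e-09, and 0.0148 with an estimated correlation), among them P4HA2, a collagen prolyl hydroxylase (0.54 ± 0.06, adjusted p = 7.68e-06), and NDRG1 (0.50 ± 0.09). The mean level of the list was 4.84 ± 0.31 log2(CPM + 1) at day 14 (n = 3), 6.54 ± 0.30 at day 16 (n = 4) and 5.65 ± 0.17 at day 17 (n = 3). Of 9 genes of primed pluripotency 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 1.73e-05, and 0.0144 with an estimated correlation), OTX2 by 1.23 ± 0.22 and ZIC2 by 0.87 ± 0.18. At day 17 OTX2 stood at 39.7 ± 20.6 CPM in EXMC and 308 ± 16.3 in EPI, and ZIC2 at 27.6 ± 14.6 and 163 ± 5.20, so RNA of EPI cells is open as a source of part of these rises. The same holds for SFRP1, at 163.3 ± 41.7 CPM in EXMC and 965.8 ± 105 in EPI when the sums of all types were scaled together. Of 19 EXMC genes 10 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 4.87e-05, and 0.203 with an estimated correlation). Of 12 mesenchymal transition genes 7 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.67e-04, and 0.102 with an estimated correlation), FN1, fibronectin, by 0.25 ± 0.05. Of 13 trophoblast genes 5 fell (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.87e-05, and 0.203 with an estimated correlation), CGA at -0.81 ± 0.18. CGA was counted in 236 of 243 EXMC cells of days 11 to 14 (median 789 CPM). NPPA (-1.15 ± 0.17), the dynein chain DNAH7 (-1.15 ± 0.28) and the transporter SLCO4C1 (-0.72 ± 0.11) were among the largest falls.

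Over 19 EXMC sums with 479 cells, 1303 of 11056 genes were called, of which 790 rose and 513 fell. Among embryos with developmental stage labels 1088 were called, 1549 with the label type as a covariate, and 1216 without genes at least 8 times higher in another type. Of the 77 called genes so left out, 54 were rises. Without day 16 the count fell to 586, the calls of CXCL14, DCN, DNAH7, CGA and HAND1 were lost and OTX2 was too low to be tested. With 1 embryo left out, the call was lost in 1 of 19 fits for GATA4.

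**Figure D4:**
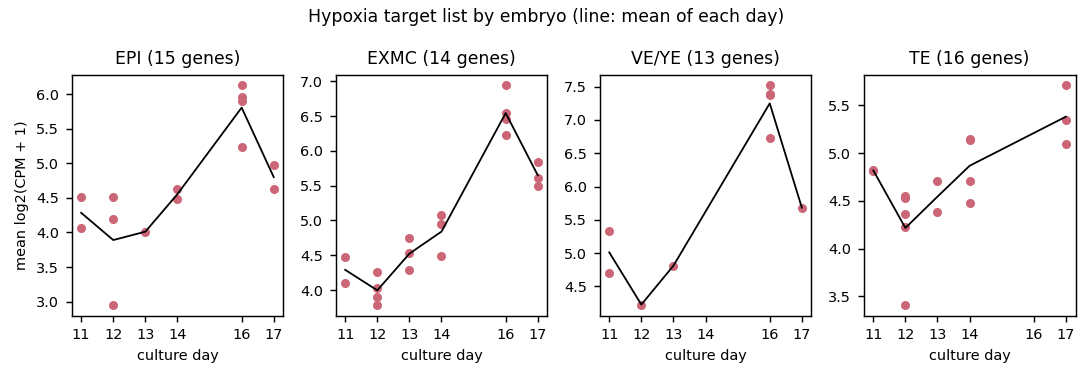
Mean log2(CPM + 1) of the measured hypoxia targets in each embryo's EPI, EXMC, VE/YE and TE sums against labelled day, with a line through the mean of each day (axes differ between panels). In EXMC the mean is 6.54 at day 16 and 5.65 at day 17, and TE has no sum at day 16.

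In TE, DLK1, PRG2 and MMP12 rose with day and CCR7 and DIO1 fell. DLK1 rose by 2.18 ± 0.18 log2 per day (adjusted p = 8.12e-06). PRG2, the eosinophil major basic protein that placenta also makes, rose by 1.84 ± 0.44 (adjusted p = 0.0126), from 17.5 ± 8.58 CPM at day 11 (n = 2) to 6639 ± 5189 at day 17 (n = 3). The elastase MMP12 rose by 2.00 ± 0.48 (adjusted p = 0.0135). TIMP3, a metalloproteinase inhibitor, and CLDN19, a tight junction protein, rose by 1.68 ± 0.33 and 1.65 ± 0.29. CCR7 fell (-1.22 ± 0.25, adjusted p = 0.00564), from 655 ± 38.5 CPM at day 11 to 1.08 ± 1.87 at day 17, and so did the deiodinase DIO1 (-1.31 ± 0.23, adjusted p = 0.00118). The trophoblast regulators GATA2 (-0.43 ± 0.12, adjusted p = 0.0207) and TFAP2A (-0.30 ± 0.08, adjusted p = 0.0142) fell, while GATA3 (-0.07 ± 0.07, adjusted p = 0.497) and TFAP2C (-0.21 ± 0.10, adjusted p = 0.181) were not called. CGA averaged 14426 CPM over the 356 TE cells of days 11 to 14 and 116.5 over the 24 of days 16 and 17. The label, TE and derivatives, is not split further. Changes within its cells thus cannot be told apart from a shift in the kinds of cell under it.

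Another large rise in TE was that of C7H15orf48 (1.80 ± 0.56), and other large falls were those of C4BPA (-1.69 ± 0.53), DEGS2 (-1.60 ± 0.36), TUBB4 (-1.58 ± 0.32), HIF3A (-1.33 ± 0.35) and BCAS1 (-1.31 ± 0.30). Of 15 trophoblast genes 5 fell (8 adjusted over the list alone; camera adjusted p = 0.00115, and 0.321 with an estimated correlation). Of 18 EXMC genes 11 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 4.55e-09, and 0.119 with an estimated correlation), COL1A1 by 0.82 ± 0.11 and COL1A2 by 0.83 ± 0.12. Of 11 mesenchymal transition genes 3 rose (5 adjusted over the list alone; camera adjusted p = 9.42e-05, and 0.119 with an estimated correlation), TGFBI by 1.00 ± 0.14 and COL5A1 by 0.80 ± 0.14. Of 10 primed pluripotency genes 6 rose (8 adjusted over the list alone; camera adjusted p = 1.68e-05, and 0.119 with an estimated correlation), CRABP1, a retinoic acid binding protein, by 1.45 ± 0.20. Of 31 genes of oxidative phosphorylation 6 fell (6 adjusted over the list alone; camera adjusted p = 0.00105, and 0.505 with an estimated correlation), NDUFS3 at -0.39 ± 0.08. Over 16 TE sums with 376 cells, 1813 of 12205 genes were called, of which 985 rose and 828 fell. Without genes at least 8 times higher in another type 1627 were called, of which 814 rose and 813 fell, so that 166 of the 171 called genes left out were rises. The excess of rises over falls in TE is thus open to RNA of other types. No TE sum came from day 16, and 2 of the 3 from day 17 had culture stage labels. Without replicate 1 of day 17 the count was 1052, without replicate 2 it was 1177, with developmental stage labels alone 240 and with the label type as a covariate 1215. Leaving out 1 embryo ended the call in 10 of 16 fits for C4BPA and C7H15orf48, 3 of 16 fits for GATA2 and 1 of 16 fits for TIMP3.

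In VE/YE, the endoderm that lines the yolk sac, few genes passed. LDHA, lactate dehydrogenase, rose by 1.58 ± 0.31 log2 per day (adjusted p = 0.0390), with no count at day 11 (n = 2), 78.8 ± 28.2 CPM at day 16 (n = 4) and 6.99 at day 17 (n = 1). PFKFB4, which sets the rate of glycolysis, rose by 0.90 ± 0.17 (adjusted p = 0.0350), and so did DCN (1.51 ± 0.28; 80.0 ± 66.4 CPM at day 16 against 2423 ± 1010 in EXMC), the calcium regulator STC1 (1.37 ± 0.28), CELF2 (adjusted p = 0.0367) and SAMD12 (1.06 ± 0.18). KANK4 was the 1 fall (-0.85 ± 0.16, adjusted p = 0.0350). APOA1, the main protein of HDL particles, was not called (-0.16 ± 0.07, adjusted p = 0.498), nor were GATA4, GATA6, FOXA2, CER1 and SOX17 (adjusted p from 0.908 for CER1 to 0.969 for SOX17). Of 13 hypoxia targets 1 rose (8 adjusted over the list alone; camera adjusted p = 1.16e-09, and 0.302 with an estimated correlation). Of 14 glycolysis genes 1 rose (10 adjusted over the list alone; camera adjusted p = 1.79e-08, and 0.302 with an estimated correlation). The mean level of the glycolysis list was 6.208 ± 0.093 log2(CPM + 1) at day 11, 8.395 ± 0.245 at day 16 and 6.335 at day 17. PFKFB4 stood at 234.5 ± 98.8 CPM at day 16 and 31.45 at day 17. These rises are thus those of day 16 and do not last to the 1 sum of day 17. Over 9 sums with 75 cells edgeR called 11 of 7602 genes, 10 rising. Without genes at least 8 times higher in another type, DCN among them, 10 were called, and RNA of EXMC cells is open as a source of the DCN rise. The count depended on single embryos, from 0 without replicate 1 of day 11 to 123 without replicate 3 of day 17, and 23 genes were called without day 16, none of them among the 11, with CER1 now called (-1.04, adjusted p = 0.0268). With 1 embryo left out, the call was lost in 8 of 9 fits for PFKFB4, 5 of 6 fits for CELF2, 4 of 5 fits for LDHA, 7 of 9 fits for STC1, 5 of 9 fits for KANK4, 3 of 6 fits for DCN and 3 of 9 fits for SAMD12.

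Whether the change with day differed between EPI, EXMC, TE and VE/YE was tested over 57 sums of 20 embryos, and 968 of 17430 genes differed. The 12 with the lowest p, with the change of each type, stand with the results for a closer look. With developmental stage labels alone the count was 224. TE had no sum at day 16, and without that day 999 genes differed, 612 of them among the 968.

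Compared with EPI of the same 6 embryos, AM cells were higher in amnion and epithelial genes and lower in core pluripotency genes. ATP12A, a proton pump, was higher by 7.71 ± 0.49 log2 (adjusted p = 1.29e-09) at 187 ± 174 against 0.673 ± 0.693 CPM. BMP4, a morphogen, was higher by 4.50 ± 0.38 (adjusted p = 1.29e-07) at 201 ± 108 against 8.78 ± 3.76 CPM, and both genes were higher in 6 of 6 embryos. The amnion regulators ISL1 (5.49 ± 0.68, adjusted p = 2.45e-05), GATA3 (4.38 ± 0.44, adjusted p = 1.46e-06), TFAP2A (4.69 ± 0.95, adjusted p = 0.0260), TFAP2C (3.49 ± 0.53, adjusted p = 3.07e-04) and HAND1 (5.31 ± 0.60, adjusted p = 0.00146) were higher, in 6 of 6 embryos each. SOX2 (-3.08 ± 0.37, adjusted p = 2.04e-05), NANOG (-1.72 ± 0.36, adjusted p = 0.00547) and the DNA methyltransferase DNMT3B (-1.58 ± 0.22, adjusted p = 2e-04) were lower, and POU5F1 (-0.53 ± 0.18, adjusted p = 0.101) was not called. WNT6, with 2 counts in EPI, was 183-fold (95% counting interval 49.9 to 1526) higher, 114-fold without replicate 3 of day 16, and ST8SIA2, with none, at least 95.5-fold higher.

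Of 18 amnion genes 13 were higher in AM (14 adjusted over the list alone; camera adjusted p = 8.65e-43, and 0.0394 with an estimated correlation), IGFBP5 by 5.83 ± 0.42 and GABRP, a GABA receptor subunit, by 6.61 ± 0.73. Of 12 epithelial genes 6 were higher (6 adjusted over the list alone; camera adjusted p = 1.26e-18, and 0.0394 with an estimated correlation), KRT8 by 3.47 ± 0.25 and KRT19 by 3.07 ± 0.29. Of 12 core pluripotency genes 6 were lower (9 adjusted over the list alone; camera adjusted p = 5.14e-08, and 0.0463 with an estimated correlation), PRDM14 at -2.92 ± 0.56. Of 14 HOX genes, which pattern the body axis, 4 were higher (8 adjusted over the list alone; camera adjusted p = 1.11e-07, and 0.150 with an estimated correlation), HOXA10 by 5.00 ± 0.92. Of 9 BMP targets 4 were higher (5 adjusted over the list alone; camera adjusted p = 2.57e-07, and 0.150 with an estimated correlation), BAMBI by 2.31 ± 0.34. In all 629 of 13582 genes differed, 368 higher and 261 lower in AM. DLK2 (8.48 ± 0.75) and CXHXorf48 (6.96 ± 1.02) were among the largest rises. TFEC, with 1 count in AM, was 448-fold (95% counting interval 80.2 to 17690) lower. Replicate 4 of day 16 held 79.5% of the ST8SIA2 counts and replicate 1 65.3% of those of TFEC, and without them both genes had bounds, of 17.6 and 47.8. The sums came from days 12 and 16 and mix early and late AM labels. Without replicate 2 of day 16 the count was 342 and without replicate 3 it was 362. Among embryos with developmental stage labels 485 genes were called. Leaving out 1 embryo ended the call in 3 of 6 fits for TFAP2A and 1 of 6 fits for ST8SIA2.

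Gast cells of 6 embryos were higher than EPI in genes of the primitive streak and in WNT and BMP targets. LEF1, a WNT effector, was higher by 5.27 ± 0.65 log2 (adjusted p = 8.04e-04) at 88.0 ± 28.3 against 2.69 ± 2.27 CPM. ID2, a BMP target, was higher by 3.17 ± 0.22 (adjusted p = 5.86e-07) at 329 ± 93.3 against 36.6 ± 8.33 CPM, and both genes were higher in 6 of 6 embryos. TBXT, which drives mesoderm formation, was higher (4.23 ± 0.91, adjusted p = 0.0306) at 39.2 ± 36.1 against 4.20 ± 6.55 CPM, and MESP1, an early mesoderm factor with 1 count in EPI, was 581-fold (95% counting interval 103 to 23070) higher, and at least 65.6-fold without replicate 4 of day 16, which held 67.2% of its Gast counts. HAND1 (5.06 ± 0.50, adjusted p = 0.00110), GATA4 (3.45 ± 0.61, adjusted p = 0.0109) and the growth factor HGF (3.19 ± 0.36, adjusted p = 3.71e-04) were higher. The sums mix E-Gast cells of day 14 with L-Gast1 and L-Gast2 cells of day 16. In E-Gast, L-Gast1 and L-Gast2, HAND1 averaged 23.6, 22.9 and 583 CPM and MESP1 0, 2.95 and 66.5 CPM. Their rises are thus mostly those of L-Gast2. TBXT ran the other way, at 77.2, 38.0 and 22.1 CPM. EOMES (3.23 ± 0.76, adjusted p = 0.0545), MIXL1 (3.44 ± 1.63, adjusted p = 0.363), SOX2 (-2.80 ± 0.72, adjusted p = 0.147), NANOG (-1.41 ± 0.35, adjusted p = 0.0759), DNMT3B (-1.47 ± 0.30, adjusted p = 0.0809) and POU5F1 (-0.95 ± 0.34, adjusted p = 0.286) were not called.

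Of 14 streak genes 3 were higher in Gast (6 adjusted over the list alone; camera adjusted p = 2.12e-11, and 0.0379 with an estimated correlation). Of 10 WNT targets 3 were higher (5 adjusted over the list alone; camera adjusted p = 2.29e-09, and 0.0186 with an estimated correlation), SP5 by 3.36 ± 0.68. Of 9 BMP targets 3 were higher (5 adjusted over the list alone; camera adjusted p = 1.74e-12, and 0.0169 with an estimated correlation), ID3 by 1.55 ± 0.23. Of 14 HOX genes 5 were higher (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.89e-11, and 0.0379 with an estimated correlation), HOXB6 by 5.51 ± 1.11. Of 18 EXMC genes 5 were higher (9 adjusted over the list alone; camera adjusted p = 1.66e-21, and 0.0422 with an estimated correlation). FGF17 (5.93 ± 1.20), the WNT antagonist DKK1 (5.54 ± 1.06), KEL (5.50 ± 1.07) and HLX (5.34 ± 0.98) were among the largest rises. PURG (-5.62 ± 0.57), SCN2A (-5.12 ± 0.69) and SYTL3 (-5.03 ± 0.47) were among the largest falls. Replicate 4 of day 16 held 71.5%, 75.8% and 69.9% of their EPI counts, and without it PURG was too low to be tested, SCN2A was not called and SYTL3 was still called. In all 178 of 14973 genes differed, 83 higher and 95 lower. The sums came from days 14 and 16. Without replicate 1, 2 or 3 of day 16 the counts were 61, 57 and 54, and with at least 10 cells per sum 57. With 1 embryo left out, the call was lost in 5 of 6 fits for FGF17, 4 of 6 fits for KEL, SP5 and TBXT, 3 of 6 fits for DKK1 and HOXB6, 2 of 6 fits for GATA4 and HLX and 1 of 6 fits for MESP1 and SCN2A.

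PGC cells of 3 day 16 embryos were higher than EPI in SOX17, NANOS3 and TFAP2C and lower in SOX2 and DNMT3B. SOX17, which specifies primate germ cells, was higher by 8.20 ± 0.98 log2 (adjusted p = 3.35e-14) at 167 ± 62.3 against 0.596 ± 0.535 CPM. NANOS3, which guards germ cell survival, was higher by 6.49 ± 0.94 (adjusted p = 1.29e-09), and TFAP2C by 5.87 ± 0.80 (adjusted p = 8.63e-11), and all 3 genes were higher in 3 of 3 embryos. TBXT, with 1 count in EPI, was 1098-fold (95% counting interval 195 to 43580) higher and PRDM1, with 3, 419-fold (95% counting interval 142 to 2044) higher. Without the embryo with the most counts these were at least 236-fold (replicate 3) and 256-fold (replicate 2). SOX2 was lower (-5.86 ± 0.65, adjusted p = 1.13e-16), as was DNMT3B (-4.00 ± 0.34, adjusted p = 4.37e-29) at 74.1 ± 33.2 against 1149 ± 121 CPM. With 3 embryos, the adjusted p-values of this comparison rest largely on a spread estimated over many genes. They do not measure how much PGC cells vary between embryos. POU5F1 (0.26 ± 0.24, adjusted p = 0.728) and NANOG (-0.12 ± 0.51, adjusted p = 0.964) were not called.

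Of 11 germ cell genes 7 were higher (7 adjusted over the list alone; camera adjusted p = 5.56e-17, and 0.204 with an estimated correlation), PDPN, a surface glycoprotein, by 3.28 ± 0.38. Of 8 streak genes 3 were higher (3 adjusted over the list alone; camera adjusted p = 4.38e-04, and 0.204 with an estimated correlation), WNT3 by 5.68 ± 1.38 and CDX2 by 5.07 ± 1.60. Of 16 EXMC genes 3 were higher (3 adjusted over the list alone; camera adjusted p = 5.88e-05, and 0.204 with an estimated correlation), VIM by 2.93 ± 0.38. Of 15 amnion genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 4.58e-04, and 0.204 with an estimated correlation), VTCN1 lower at -4.84 ± 0.92. PDGFB was at least 154-fold, HES6 at least 77.2-fold and TMEM229A at least 69.0-fold higher, with no count in EPI. NTN4, SLCO3A1, WDR88 and TNR had no count in PGC and were at least 37.2-fold, at least 19.7-fold, at least 26.9-fold and at least 20.6-fold lower. Replicate 2 of day 16 held 92.2%, 44.7%, 92.4% and 83.9% of their EPI counts, and without it the bounds were 3.20, 12.0, 2.23 and 3.64, with all but SLCO3A1 too low to be tested. Replicate 3 held 85.1%, 76.6% and 76.2% of the PGC counts of PDGFB, HES6 and TMEM229A, whose bounds without it were 39.9, 31.3 and 28.5. In all 433 of 12079 genes differed, 161 higher and 272 lower. The median change of all genes was -0.40 with TMM and -0.30 with size factors. Without replicate 2 of day 16 the count was 242 and without replicate 3 it was 139. Leaving out 1 embryo ended the call in 1 of 1 fits for WDR88, 2 of 3 fits for CDX2, SLCO3A1 and WNT3, 1 of 2 fits for HES6 and 1 of 3 fits for NANOS3 and VTCN1.

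VE/YE cells of 7 embryos were higher than EPI in genes of visceral endoderm and of secreted antagonists. TTR, a thyroid hormone carrier, was higher by 8.13 ± 0.27 log2 (adjusted p = 1.79e-15) and APOA1 by 7.27 ± 0.72 (adjusted p = 6.92e-04) at 11560 ± 3414 against 160.2 ± 279 CPM. CER1, which blocks NODAL and BMP signals, was higher by 8.77 ± 0.46 (adjusted p = 1e-11), and all 3 genes were higher in 7 of 7 embryos. The endoderm regulators GATA4 (5.46 ± 0.42, adjusted p = 6.89e-09), GATA6 (4.85 ± 0.67, adjusted p = 6.08e-05), SOX17 (5.24 ± 0.70, adjusted p = 8.52e-06) and FOXA2 (4.53 ± 0.93, adjusted p = 0.00154) were higher. POU5F1 (-4.26 ± 0.38, adjusted p = 4.31e-06), NANOG (-5.58 ± 0.57, adjusted p = 2.55e-07) and SOX2 (-5.38 ± 0.63, adjusted p = 1.13e-05) were lower.

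Of 17 visceral endoderm genes 16 were higher (16 adjusted over the list alone; camera adjusted p = 9.94e-35, and 0.00496 with an estimated correlation), HNF4A by 7.35 ± 0.65. All 8 anterior endoderm genes were higher (8 adjusted over the list alone; camera adjusted p = 1.19e-18, and 0.00201 with an estimated correlation), among them DKK1 (7.89 ± 0.70), LEFTY1 (4.24 ± 0.44) and LHX1, which with 2 counts in EPI was 744-fold (95% counting interval 205 to 6161) higher and 1222-fold without replicate 1 of day 16. All 7 genes of definitive endoderm and node were higher as well (7 adjusted over the list alone; camera adjusted p = 9.32e-16, and 0.00201 with an estimated correlation), CXCR4 by 6.84 ± 0.52. Of 12 core pluripotency genes 10 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 1.62e-10, and 0.0134 with an estimated correlation). Of 12 epithelial genes 7 were higher (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.4e-07, and 0.0325 with an estimated correlation), DSP, desmoplakin, by 3.18 ± 0.25. CTSE was 876-fold (95% counting interval 299 to 4258) and APOC3 820.4-fold (95% counting interval 226 to 6792) higher, and DPYSL5 at least 54.3-fold lower. In all 2716 of 12044 genes differed, 1164 higher and 1552 lower. With at least 10 cells per sum the count was 805.

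EXMC cells of 13 embryos were higher than EPI in genes of extraembryonic mesenchyme, mesenchymal transition and HOX. COL6A1, a chain of type VI collagen, was higher by 5.21 ± 0.40 log2 (adjusted p = 6.45e-07) at 1215 ± 749 against 41.2 ± 34.5 CPM. TBX20, a mesoderm factor, was higher by 5.06 ± 0.33 (adjusted p = 5.22e-12), and both genes were higher in 13 of 13 embryos. The growth factor receptor PDGFRA (6.01 ± 0.46, adjusted p = 1.3e-10), HOXA10 (6.25 ± 0.50, adjusted p = 2.35e-09), GATA6 (4.85 ± 0.46, adjusted p = 4.54e-08) and GATA4 (4.58 ± 0.49, adjusted p = 1.61e-06) were higher, as was HAND1 (4.55 ± 0.53, adjusted p = 2.06e-05). POU5F1 (-3.97 ± 0.72, adjusted p = 0.00112), NANOG (-4.28 ± 0.73, adjusted p = 5.85e-04), SOX2 (-4.13 ± 0.62, adjusted p = 2.16e-04) and DNMT3B (-3.39 ± 0.31, adjusted p = 2.56e-06) were lower.

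All 19 EXMC genes were higher (19 adjusted over the list alone; camera adjusted p = 9.84e-55, and 6.68e-04 with an estimated correlation), as were all 13 mesenchymal transition genes (13 adjusted over the list alone; camera adjusted p = 3.25e-28, and 6.68e-04 with an estimated correlation), COL5A1 by 4.99 ± 0.25. Of 19 HOX genes 16 were higher (17 adjusted over the list alone; camera adjusted p = 1.11e-12, and 0.00147 with an estimated correlation), HOXC8 by 5.59 ± 0.61. Of 17 amnion genes 7 were higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 4.34e-06, and 0.0177 with an estimated correlation), IGFBP3, an IGF carrier, higher by 4.70 ± 0.27 and VTCN1 lower at -2.31 ± 0.35. Of 13 primed pluripotency genes 7 were lower (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.3e-05, and 0.00907 with an estimated correlation), SFRP1 at -2.94 ± 0.30. The transcription factors OSR1 (6.63 ± 0.58) and FOXF1 (6.21 ± 0.63) were among the largest rises. In all 4594 of 15464 genes differed, 2197 higher and 2397 lower. Among embryos with developmental stage labels 3403 genes were called.

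TE cells of 10 embryos were higher than EPI in trophoblast genes and lower in pluripotency genes. GATA3 was higher by 4.98 ± 0.30 log2 (adjusted p = 2.24e-09) at 533 ± 192 against 17.9 ± 11.0 CPM. GCM1, which drives syncytiotrophoblast formation, was higher by 5.09 ± 0.36 (adjusted p = 3.21e-08), and INSL4, an insulin-like placental peptide, by 6.22 ± 0.34 (adjusted p = 7.42e-10), and all 3 genes were higher in 10 of 10 embryos. GATA2 (4.22 ± 0.43, adjusted p = 9.39e-06), TFAP2A (4.72 ± 0.52, adjusted p = 1.73e-05) and TFAP2C (2.62 ± 0.32, adjusted p = 2.79e-06) were higher. POU5F1 (-4.83 ± 0.68, adjusted p = 2.71e-04), NANOG (-5.57 ± 0.59, adjusted p = 2.88e-06), SOX2 (-5.56 ± 0.74, adjusted p = 8.7e-05) and DNMT3B (-3.28 ± 0.23, adjusted p = 1.14e-08) were lower.

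Of 16 trophoblast genes 13 were higher in TE (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.78e-13, and 0.0360 with an estimated correlation). Of 17 amnion genes 11 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 4.76e-05, and 0.117 with an estimated correlation), DLX5 by 3.96 ± 0.50. GATA2, GATA3 and KRT7 stand on both lists. Of 12 core pluripotency genes 11 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 7.94e-10, and 0.0360 with an estimated correlation). Of 13 primed pluripotency genes 11 were lower (12 adjusted over the list alone; camera adjusted p = 2.14e-08, and 0.00393 with an estimated correlation), THY1 at -5.30 ± 0.54. The cytokine IL1B (6.88 ± 0.65), KRT17 (6.50 ± 0.80), the placental protease HTRA4 (6.18 ± 0.93) and LAIR1 (6.08 ± 0.71) were among the largest rises. Their TE levels were uneven between embryos, at 110.5 ± 241.4, 45.4 ± 122.5, 263.8 ± 582.5 and 28.8 ± 52.4 CPM. CCL20 (-7.26 ± 0.63), VENTX (-7.17 ± 0.76), DPPA5 (-6.27 ± 0.67) and FGF19 (-6.13 ± 0.54) were among the largest falls. In all 6609 of 15159 genes differed, 3161 higher and 3448 lower. Among embryos with developmental stage labels 6131 genes were called.

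**Figure D5:**
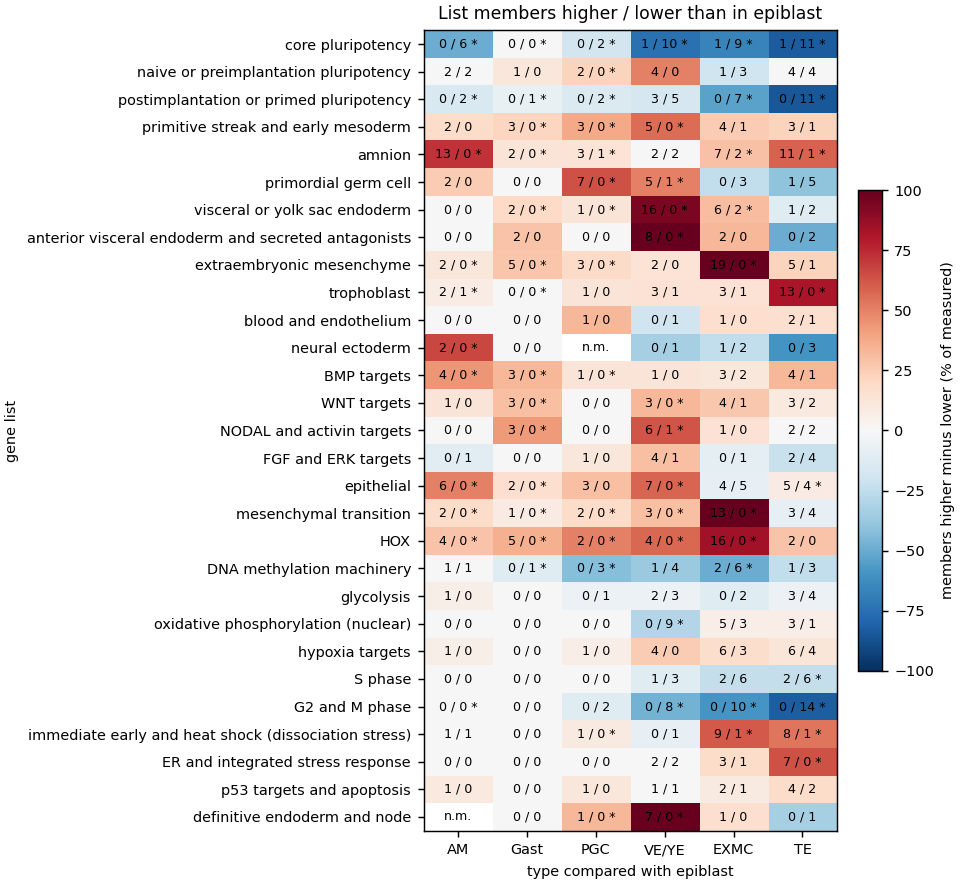
Members of each gene list that were higher / lower than in EPI (numbers in each cell), with rows for lists, columns for the type compared with EPI, color for the difference of both counts in percent of the measured members and a star where the camera test passed with the preset correlation. The VE/YE column holds 16 / 0 for visceral endoderm and the EXMC column 19 / 0 for extraembryonic mesenchyme.

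The late Gast label is split in the annotation, and L-Gast2 was compared with L-Gast1 in the 4 embryos of day 16. HAND1 was higher in L-Gast2 by 4.81 ± 0.53 log2 (adjusted p = 5.8e-09) at 605 ± 191 against 21.9 ± 14.6 CPM. Higher as well were the cadherin CDH11 by 5.66 ± 0.81 (adjusted p = 1.72e-06), HGF by 4.78 ± 0.59 (adjusted p = 9.04e-08) and BMP4 by 6.53 ± 0.91 (adjusted p = 1.42e-04), each in 4 of 4 embryos. HOXB6 was at least 32.6-fold, FOSL2 at least 45.9-fold, PITX1 at least 35.3-fold and TNC at least 24.5-fold higher, with no count in L-Gast1, and without the embryo with the most counts (replicates 2, 3, 4 and 2) the bounds were 17.2, 16.4, 19.9 and 9.85. GDF3, a TGF-beta ligand of pluripotent cells (-4.95 ± 0.75, adjusted p = 5.07e-06), NANOG (-4.01 ± 0.96, adjusted p = 0.00955) and POU5F1 (adjusted p = 5.87e-04) were lower, POU5F1 at 218 ± 187 against 655 ± 166 CPM. TBXT (-2.71 ± 1.75, adjusted p = 0.639) and EOMES (-3.01 ± 0.97, adjusted p = 0.112) were not called, and MESP1 was 19.9-fold (95% counting interval 6.70 to 97.4) higher by its counts and 10.95-fold without replicate 4 (adjusted p = 0.417). Of 17 EXMC genes 8 were higher (14 adjusted over the list alone; camera adjusted p = 3.66e-20, and 0.133 with an estimated correlation). Of 12 core pluripotency genes 4 were lower (8 adjusted over the list alone; camera adjusted p = 2.53e-10, and 0.109 with an estimated correlation). Of 6 HOX genes 2 were higher (6 adjusted over the list alone; camera adjusted p = 5.47e-06, and 0.292 with an estimated correlation). In all 210 of 8815 genes differed, 143 higher and 67 lower in L-Gast2. Without replicate 2 of day 16 the count was 112 and without replicate 3 it was 61. With 1 embryo left out, the call was lost in 3 of 4 fits for NANOG and 1 of 4 fits for FOSL2 and PITX1.

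L-AM2 was compared with L-AM1 in 3 day 16 embryos. The keratins KRT18 (3.51 ± 0.34, adjusted p = 4.36e-04) and KRT8 (2.80 ± 0.33, adjusted p = 0.00275) were higher in L-AM2, KRT18 at 2879 ± 134 against 289 ± 187 CPM, as were CXCL14 (3.64 ± 0.47, adjusted p = 0.00347), FN1 (2.10 ± 0.30, adjusted p = 0.00971), ATP12A (4.68 ± 0.72, adjusted p = 0.0126), DLK2 (5.14 ± 0.87), TGFBI (4.42 ± 0.78) and HAPLN1 (3.88 ± 0.70). DNMT3B was lower (-3.95 ± 0.64, adjusted p = 0.0190) at 56.1 ± 38.4 against 822 ± 222 CPM, as were RHCE (-7.92 ± 1.15, in 2 of 3 embryos), PLCXD2 (-3.25 ± 0.55) and SSB (-1.90 ± 0.29). RHCE varied widely between embryos in L-AM1, at 512.7 ± 848.5 CPM, so its change is not that of a typical embryo. Of 15 amnion genes none was called over all genes and 9 were higher adjusted over the list alone (camera adjusted p = 8.83e-12, and 0.372 with an estimated correlation). Of 10 epithelial genes 2 were higher (5 adjusted over the list alone; camera adjusted p = 1.56e-07, and 0.577 with an estimated correlation). In all edgeR called 17 of 8481 genes, 12 higher and 5 lower. Without replicate 1 of day 16 the count was 61 and without replicate 4 it was 108, and DESeq2 called 229. Leaving out 1 embryo ended the call in 1 of 3 fits for DLK2, SSB and TGFBI.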

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

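Chosen only after the result was seen were the tests of one cell type's RNA and of a steady rise for the hypoxia targets, the tests of a scaling error in EPI and VE/YE, the tests of a few TE cells named EXMC or VE/YE, the test of EXMC RNA in EPI, the tests of a wrong day label, the errors on days left out, the counts without day 16 and the counts without genes at least 8 times higher in another type.

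The change with day differed between EPI, EXMC, TE and VE/YE for 968 genes by a test of the difference itself (edgeR interaction of type and day). Named here are the 12 with the lowest p, as log2 per day in EPI, EXMC, TE and VE/YE in that order. BNIP3, a mitochondrial hypoxia target, changed by 0.17 ± 0.10, 0.60 ± 0.14, 0.42 ± 0.06 and 0.34 ± 0.11 (adjusted p = 1.57e-06). It stood highest at day 16 in EPI, EXMC and VE/YE, at 2170 ± 1051, 1759 ± 760.2 and 2858 ± 1170 CPM, and at 594 ± 227, 291 ± 78.2 and 391 at day 17, and TE had no sum at day 16, so its changes per day cover other days. Without day 16 the difference was still called (adjusted p = 0.00022), as was that of the other 11 genes below. SRI, a calcium-binding protein, rose in TE and was not called in the others, with -0.13 ± 0.06, -0.01 ± 0.06, 0.68 ± 0.07 and -0.06 ± 0.08 (adjusted p = 1.57e-06). CHD7, a chromatin remodeler, rose in EPI and was not called in the others, with 0.80 ± 0.10, 0.09 ± 0.05, -0.06 ± 0.06 and 0.19 ± 0.09 (adjusted p = 3.86e-06). SFRP1, a secreted WNT antagonist, had 1.06 ± 0.09, 1.39 ± 0.12, 0.85 ± 0.13 and 0.12 ± 0.13 (adjusted p = 4.97e-06). At day 17 it stood at 965.8 ± 105, 163.3 ± 41.7 and 63.5 ± 47.1 CPM in EPI, EXMC and TE. RNA of EPI cells is thus open as a source of part of its EXMC and TE rises. FXYD5, a regulator of the sodium pump, had -0.38 ± 0.07, 0.37 ± 0.09 and 0.74 ± 0.14 in EPI, EXMC and TE and was not tested in VE/YE (adjusted p = 6.95e-06). DIP2C had -0.85 ± 0.10, -0.12 ± 0.04, 0.18 ± 0.07 and 0.31 ± 0.12 (adjusted p = 7.48e-06). CAPG, an actin-capping protein, had -0.25 ± 0.06, -0.26 ± 0.07, 0.57 ± 0.08 and -0.40 ± 0.14 (adjusted p = 8.81e-06). LGALS1, a galectin, had -0.69 ± 0.07, 0.13 ± 0.05, 0.36 ± 0.20 and 0.02 ± 0.16 (adjusted p = 1.89e-05). AMOTL1, an angiomotin of cell junctions, had -0.20 ± 0.10, 0.02 ± 0.06, -0.49 ± 0.09 and 0.02 ± 0.11 (adjusted p = 2.44e-05). NREP had 0.32 ± 0.05, 0.92 ± 0.10, 0.64 ± 0.13 and 0.79 ± 0.15 (adjusted p = 2.44e-05). FGD6 had -0.16 ± 0.08, 0.08 ± 0.07, -0.59 ± 0.12 and 0.27 ± 0.13 (adjusted p = 3.06e-05). FSTL1, a secreted follistatin-like protein, had 0.14 ± 0.07, 0.01 ± 0.05, 0.67 ± 0.08 and 0.00 ± 0.10 (adjusted p = 4.27e-05).

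Replicate 3 of day 16 held 0 TE cells among 85, a share of 0% against 1 TE cell each, or 1.136% to 1.299%, in the other 3 embryos of that day. Its gap to them was 0.8745 of the range against a critical value of 0.829 for 4 samples, which a difference of 1 cell was enough to reach; among 33 such groups this was the 1 found, and chance gives about 1 in 20.

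Hypoxia targets stood highest in the day 16 embryos, for 9 of 15 measured genes in EPI, 10 of 14 in EXMC and 10 of 13 in VE/YE. The mean level of the glycolysis list was higher at day 16 as well, by 1.468, 1.508 and 2.1 log2 against the other days in EPI, EXMC and VE/YE. RNA of one cell type spread over the other cells is argued against by how close the levels of the 3 types lay, with a median ratio of lowest to highest type of 0.4309 over 17 genes (quartiles 0.2425 to 0.5839), where EXMC genes reached a ratio of 0.02853 in EPI. A steady rise leaves unexplained the EXMC mean, which changed by -0.8937 log2 from day 16 to day 17, though this restates the pattern (n = 4 and 3). A scaling error for all genes is argued against in EXMC and VE/YE, where oxidative phosphorylation stood 0.2278 and 0.622 log2 above the other days and hypoxia targets 1.902 and 2.3 above, but that list leaves it open for part of the rise in EPI, at 0.7454 (SE 0.1627) against 1.507. S phase genes in EPI stood at 6.238 ± 0.475 log2(CPM + 1) at day 16 (n = 4) against day means of 6.428 to 6.589. G2 and M phase genes stood at 7.494 ± 0.133 against 7.023 to 7.321. The S phase genes argue against a shift of all EPI genes by 0.7454, while a smaller one stays open. Left open and untested are culture conditions or handling of the day 16 embryos and a stage of development at day 16, which cannot be told apart because both are tied to the day itself and no label names a batch.

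Transcripts of extraembryonic types were counted in cells of other types, with CGA at a median of 9.212% of its TE level in 22 EPI, EXMC and VE/YE sums of days 11 to 14 (range 3.491% to 38.86%), while at days 16 and 17 its mean over cells was 116.5 CPM in 24 TE cells and 107.1, 146.2 and 257.5 CPM in EPI, EXMC and VE/YE. A few TE cells under another name are argued against in EPI and EXMC, where the tenth of cells with the most held 33.776% and 47.516% of it at days 11 to 14, but left open for part of it in VE/YE, where those cells held 61.443% although 95.918% of the 49 cells had a count. Whether it is RNA of TE cells in other libraries cannot be told apart from low expression in those cells: the ratio of HSD3B1 to CGA lay -1.009 log2 from that in TE (quartiles -1.614 to -0.7725), and among other trophoblast genes the deviation ran from -1.785 for CCR7 to 0.2889 for KRT7. Replicate 3 of day 13, with 1 TE cell among 37, had no TE sum and is not in these ratios. Its VE/YE sum held CGA at 27.5 CPM, against 1409 ± 366 in VE/YE at day 11 (n = 2). That is 1 library of 6 cells, so it does not decide the question. For EXMC genes in EPI of day 16, RNA of EXMC cells fits by the middle of 16 genes, whose ratio to EXMC had a median of 2.853% and an upper to lower quartile of 1.345. The ends lay farther apart, from 1.554% for DCN to 5.449% for VIM. A share of the called rises of EXMC genes in EPI is therefore open to this source, and 394 genes stayed called without genes at least 8 times higher in another type.

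The day 14 embryos differed in how far their expression had moved, by a score in days from 200 genes fitted on the other days. EXMC scored 14.81 and 15.15 in replicates 1 and 3 but 12.57 in replicate 4. Sums of 2 cells, as for EXMC of replicate 2 and EPI of replicate 1, are not read. TE scored 13.33, 12.07, 15.11 and 12.36 in replicates 1 to 4. Scores on days left out of the fit missed the label by 0.5827 days in EXMC and 0.5288 in TE (root mean square). The TE error comes from days 12 and 13 alone, where the sums of day 13 missed by 0.7373 and 0.3872 days. EPI of day 16, left out in the same way, missed by -1.784 to -1.99 days. The error of TE scores at day 14 was thus not measured and may be larger. RNA of EXMC cells in TE libraries is argued against for replicate 3. Its TE stayed at least 2.82 days past that of replicates 2 and 4 without genes at least 8 times higher in another type. For replicate 1, also rich in EXMC, it is left open. Without those genes its TE scored 13.23 against 12.04 and 12.23 in replicates 2 and 4, and the gap to replicate 4 is within 2 times the TE error. Low counts are argued against by a gap of 2.13 days in EXMC after thinning. Thinning matched the counts but not the cells, which were 59, 59 and 10 in replicates 1, 3 and 4. An effect of sampling few cells was thus not tested. A wrong day label of an embryo cannot be told apart from uneven growth, since the scores of its types differed by 1.16 days in replicate 4, at least 1.33 in replicates 1 and 2 and 0.04 in replicate 3, all within 2 times the combined error, which for EPI alone was 1.382 days. No biological explanation was tested, as the design gives no group within a day.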

How the results depend on the processing

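Chosen only after the data were seen were the counts without day 16. For the changes with day, no paired analysis was possible because each embryo was collected once. A value of a named gene was counted as kept if the gene was called in both fits or in neither. Leaving out each embryo kept 4465 of 4709 values of named genes (211 weaker, 33 stronger). DESeq2 kept 381 of 439, size factors 440 of 444, no filter 413 of 444 and limma-trend 368 of 432. For 2 groups of days it was 122 of 157, for developmental labels alone 221 of 261, for 3 cells or more 256 of 272 and for 10 cells or more 224 of 271. For no block it was 154 of 175, for the label as covariate 136 of 145, for the EPI share as covariate 47 of 47 and for no day 16 105 of 137. The direction turned once, for CPS1 in Gast against EPI under DESeq2 (log2 0.46, adjusted p = 0.966). With an estimated correlation 260 of 355 list tests had the same outcome, passed in both or in neither, and 95 lists that had passed no longer did. The minimum of 20 cells for shares removed no embryo. Changes of 2 log2 over the span or between types were often missed: of 100 simulated genes 38 were found over all cells, 36 in EPI, 9 in VE/YE and 7 between L-AM2 and L-AM1.

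Where calls changed, the cause was not tested. Days 11 to 13 against 14 to 17 gave 1992 genes in all cells, 161 in EPI, 614 in EXMC, 272 in TE and 32 in VE/YE; without day 16 there were 2266, 143, 586 and, in VE/YE, 23. DESeq2 gave 1032 in EPI, 153 in VE/YE over days, 1293 for AM, 806 for Gast, 391 for L-Gast2, 229 for L-AM2 and 1475 for day by type. Limma-trend gave 710, 49, 1007 and 427 for EPI, VE/YE, AM and Gast and 75 for L-AM2. With no filter there were 1232 in EPI, 2732 in EXMC, 345 in VE/YE, 951 for AM, 391 for Gast, 83 for L-AM2 and 1720 for day by type. At least 10 cells per sum gave 653 in EXMC, 530 in TE, 57 for Gast, 805 for VE/YE against EPI and 178 for day by type, and at least 3 cells 57 in VE/YE over days and 1259 for AM. Developmental labels alone gave rho = 0.6328 for the PGC share (adjusted permutation p = 0.0233), 240 genes in TE and 224 for day by type. Without the embryo block there were 226 for AM, 47 for Gast, 129 for PGC, 1417 for VE/YE, 2730 for EXMC, 95 for L-Gast2 and 9 for L-AM2, and TE stayed within 1.5 times.

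With 1 embryo left out the EXMC share had rho from 0.4377 to 0.5778, called without replicate 3 or 5 of day 12, replicate 3 of day 13 or replicate 2 or 4 of day 14, and the TE share from -0.8433 to -0.7781. Counts ran from 275 to 503 in EPI, 937 to 1371 in EXMC, 1052 to 1892 in TE, 0 to 123 in VE/YE over days, 2903 to 3728 in all cells and 523 to 1018 for day by type. Against EPI they ran from 342 to 690 for AM, 54 to 253 for Gast, 139 to 361 for PGC, 2104 to 2609 for VE/YE, 4075 to 4522 for EXMC and 5664 to 6681 for TE, and between subtypes from 61 to 263 for L-Gast2 and 21 to 108 for L-AM2.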

Other observations

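Cell cycle and stress genes were compared between TE and EPI of 10 embryos. Of 17 G2 and M phase genes 14 were lower in TE (14 adjusted over the list alone; camera adjusted p = 9.66e-04, and 0.521 with an estimated correlation), among them the topoisomerase TOP2A (-2.09 ± 0.31, adjusted p = 1.19e-04), the spindle protein TPX2 (-1.32 ± 0.26) and the ubiquitin-conjugating enzyme UBE2C (-1.66 ± 0.34). Of 11 genes of ER stress 7 were higher (7 adjusted over the list alone; camera adjusted p = 0.00273, and 0.441 with an estimated correlation), among them the ER chaperone HSPA5 (1.45 ± 0.11, adjusted p = 1.82e-08), HERPUD1, which serves the breakdown of ER proteins (3.15 ± 0.28), and DNAJB9 (2.63 ± 0.35).

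The same list of 17 G2 and M phase genes held 8 lower in VE/YE (11 adjusted over the list alone; camera adjusted p = 6.89e-04, and 0.330 with an estimated correlation) and 10 lower in EXMC (10 adjusted over the list alone; camera adjusted p = 0.00157, and 0.500 with an estimated correlation). Of 13 immediate early and heat shock genes 9 were higher and 1 lower in EXMC (10 and 1 adjusted over the list alone; camera adjusted p = 0.00117, and 0.0257 with an estimated correlation). Of 8 genes of DNA methylation 2 were higher and 6 lower in EXMC (2 and 6 adjusted over the list alone; camera adjusted p = 0.00976, and 0.0818 with an estimated correlation), and of 7 in PGC 3 were lower (4 adjusted over the list alone; camera adjusted p = 0.00430, and 0.204 with an estimated correlation).

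Other splits of the same embryos were counted for each comparison, the real one included. As many calls as the real days or types gave came from 1 of 100 splits for all cells, EPI, EXMC and TE over days (the most in another split being 199, 42, 6 and 200), 1 of 32 for AM (21) and Gast (25), 1 of 64 for VE/YE against EPI (42), 1 of 21 for EXMC (126) and TE (0), and 1 of 25 for day by type (11 against 80 among 1200 sampled genes). For VE/YE over days it was 3 of 100 splits. Another split called 49 genes against the real 11, with a median of 0 over the other splits. This may point to a structure of these 9 samples other than the day, though what that split follows was not tested. The splits between types cannot decide, because the types were named from the same expression values and so were set to give the most calls. PGC (1 of 4), L-Gast2 (1 of 8) and L-AM2 (1 of 4) also have too few splits.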
